A study of Drosophila melanogaster with 3 samples.

How the data were processed

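ChIP-seq with an anti-GFP antibody was done on whole embryos (0 to 16 hours) of a Drosophila melanogaster line expressing GFP-tagged Runt, in 3 biological replicates numbered as in the labels. Chromatin was sonicated, per the labels. The sex of the embryos was not collected, per the labels. Peaks of each replicate were called against a control alignment shared by all 3 replicates, and further peaks were called on the pooled replicate alignments against the same control, per the readme files. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The control reads, alignments and signal tracks were not analysed here. The replicates share this control, so their lists are not fully independent.

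The deposited peak lists give for each peak a position on dm6, a signal value and a −log10 q-value. The signal value is the authors' own, its scaling is not given in the sources used here, and it was used only to rank peaks within a list. The −log10 q-value deposited by the authors was at its maximum, 3.82, for all 3065 IDR peaks, so it did not rank them. The IDR list was found to be exactly the 3065 pooled peaks with the highest signal. It holds 3064 distinct intervals, 1 of them with a pair of summits. No row was identical between replicate lists. Median widths were 344, 390 and 396 bases in replicates 1, 2 and 3, and 404 in the pooled and IDR lists. Sequencing depth is unknown, and intervals on shares of peaks cover counting error only.

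Coordinates were compared with the reference before use. The Ensembl release 115 annotation of BDGP6.54 and the Release 6 sequence have the arm lengths of dm6, and all peaks lay within them. Coordinates are printed 1-based. Gene lists, motifs, the main tests and the rule for naming genes were fixed before the data were examined. Tests and namings chosen afterwards are marked as such below. Every listed gene was matched, 5 of them through synonyms (h as hry, Dl as Delta, nos as nanos, svb as ovo, frs as Z600).

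Peaks were shared when they overlapped by at least 1 base. A summit was assigned to a promoter (within 500 bases of any annotated start), an exon, an intron or intergenic sequence, in that order. Promoter share was tested with 10000 circular shifts of summits along each arm, and overlaps were compared with 20 shifts. Motif presence within 50 bases of the summit was compared with a window of the same width centred 500 bases to 1 side, drawn at random with a fixed seed, by exact McNemar tests. A gene list was tested by exact stratified permutation over 10 classes of gene span, with all 13945 protein-coding genes on the 6 arms as background. Values for single replicates used each replicate's own 3065 strongest peaks. The 3 replicates are the only replication, and p-values over peaks or genes treat these as units.

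Genes were named by rule: run; the 20 strongest IDR peaks; from each list the 4 members with the strongest IDR peak, or every member for the pair-rule, RUNX and sex-determination lists; the 5 genes with the most summits, with ties named; and the 10 six-base sequences with the smallest p.

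Alternatives comprised stricter overlap, the 1532 strongest IDR peaks, leaving out each replicate (for results on IDR peaks after the overlaps, by keeping the 2147, 2018 or 1986 IDR peaks matched by strongest peaks of the other 2, so that these lists are also shorter), other window and gene distances, other motif forms and other strata. The planned use of the strongest pooled peaks equalled the IDR list. Added after seeing the data were the 6130 strongest pooled peaks, each replicate's own strongest peaks, local shifts, a shuffled background for six-base sequences, and strata of span and neighbour distance.

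The tests were checked on simulated data. At random sites the motif test gave p below 0.05 in 5% of 40 draws of 3065 sites, and the promoter test in 7.5% of 40 draws of 500 sites. A motif planted in 10.1% of 3065 windows was recovered as an excess of 10.2 percentage points. Shifted peaks gave a list p below 0.05 in 4.38% of list tests over 13945 genes. Simulated lists of 15 genes with a true share of 80% were found in 96% of 100 draws at unadjusted p below 0.05 and in 92% when adjusted with the 21 lists, and with a share of 60% in 67% and 43%, so lists of this size can miss such an excess. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.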

Results

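Binding of Runt was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos aged 0 to 16 hours. Runt, the product of the X-linked gene run, is a RUNX-family transcription factor known for its pair-rule role in segmentation and for its part in counting X chromosomes during sex determination. The flies carried a transgene encoding Runt with GFP at its C-terminus, and chromatin was precipitated with an antibody against GFP. The samples formed 1 group of 3 biological replicates, with no second condition, so the questions addressed were where peaks lay, how well replicates matched, and which genes and sequences the peaks marked. Each replicate's list held 30000 peaks, as did the list called on the pooled replicates. The list that passed the authors' irreproducible discovery rate (IDR) threshold held 3065. Read depth is unknown from these lists, and the fixed list length of 30000 carries no information on the number of bound sites.

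The replicates shared most of their strongest peaks and nearly every peak of the IDR list. The IDR list is the 3065 pooled peaks with the highest signal, called on the replicates' own reads, so its overlap with their lists is high in part by construction. Of the 3065 IDR peaks, 3039 (99.2%, 95% exact Clopper-Pearson interval 98.8 to 99.4, counting error only) were overlapped by at least 1 base in all 3 replicate lists. Single replicates overlapped 99.7% ± 0.0753 (SD, n = 3) of IDR peaks, against 14.6% to 15.2% after circular shifts of the peaks along each chromosome arm. When each replicate was reduced to its 3065 strongest peaks by the authors' signal value, 69.1% ± 2.36 (SD, 3 pairs of replicates) of peaks were shared between a pair, against 1.62% after shifting. In these shorter lists, 57.7% of IDR peaks were matched in all 3 replicates. Across IDR peaks, which are not independent replicates, Spearman's rho of the signal values was 0.632 for replicates 1 and 2, 0.644 for replicates 1 and 3, and 0.687 for replicates 2 and 3.

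Runt-GFP peaks lay mainly at promoters and in introns. Of the IDR summits, 1372 (44.8%) fell within 500 bases of an annotated transcription start, 1179 (38.5%) in introns and 437 (14.3%) between genes. Exons away from starts held few: 19 summits were in 5′ UTRs, 18 in 3′ UTRs, 6 in coding exons and 34 in other exons. Circularly shifted summits fell near starts in 13.2% of cases (95% of shifts, 11.7 to 14.7). The excess had p = 0.0002 in a two-sided permutation test, the smallest value that 10000 shifts can give. The replicates' own 3065 strongest peaks gave 46.4% ± 1.25 (SD, n = 3).

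The 20 strongest IDR peaks were led by a summit in an intron of CG11050 (chromosome 2L, 6612526 to 6612894, signal 1649) and one in an exon of the long non-coding RNA Vinr (chromosome X, 12750863 to 12751587, signal 1613). The third lay in an intron of ush (chromosome 2L, 480883 to 481293, signal 1520), which encodes the zinc-finger cofactor U-shaped. Most of the others were at promoters. Their nearest protein-coding starts belonged to Ugalt, CG18549, Fkbp14, CG14100, px, the glycolytic gene Gapdh2, the mitochondrial ribosomal protein genes mRpS10 and mRpL41, CG31612, CenG1A, the chromatin protein gene Chro, PNPase, aay and Tina-1. Introns of Trl, which encodes GAGA factor, and of the kinase gene Lk6 held further strong summits, and 1 intergenic summit lay nearest to CG13323. None of these 20 summits had the RUNX consensus within 50 bases.

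The X chromosome carried IDR peaks at close to the density of the autosomes. There were 510 peaks on X, or 21.7 per Mb, and 23.4 per Mb on arms 2L, 2R, 3L and 3R together. The ratio was 0.926 (95% interval 0.841 to 1.02), and the difference did not pass the exact binomial test (two-sided p = 0.118). Chromosome 4 held 6 peaks, or 4.45 per Mb. The replicates' own strongest peaks gave a ratio of 0.908 ± 0.0233 (SD, n = 3). The ratio passed the test in the list of 6130 pooled peaks (0.850, exact p = 3.04e-06) and in replicate 2 alone (0.884, p = 0.0122), and lay above 1 when peaks were counted per protein-coding gene (1.06, p = 0.207).

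The RUNX recognition sequence was enriched at the summits. The consensus TGYGGTY (Y is C or T) occurred on either strand within 50 bases of 287 of 3065 summits (9.36%, 95% exact interval 8.36 to 10.5), compared with 108 flank windows of the same width centred 500 bases away (3.52%, 2.90 to 4.24). The difference had p = 1.84e-20 in a two-sided exact McNemar test. In the replicates' own strongest peaks the shares were 8.60% ± 0.229 at summits and 3.73% ± 0.186 in flanks (SD, n = 3). In bins of 50 bases, the share was 5.48% just before the summit and 4.37% just after it, and fell to 1.79% and 1.63% in the outermost bins. The share varied with position in the genome: 6.63% of promoter summits, 10.3% of intronic summits and 14.4% of intergenic summits carried the consensus.

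**Figure D1:**
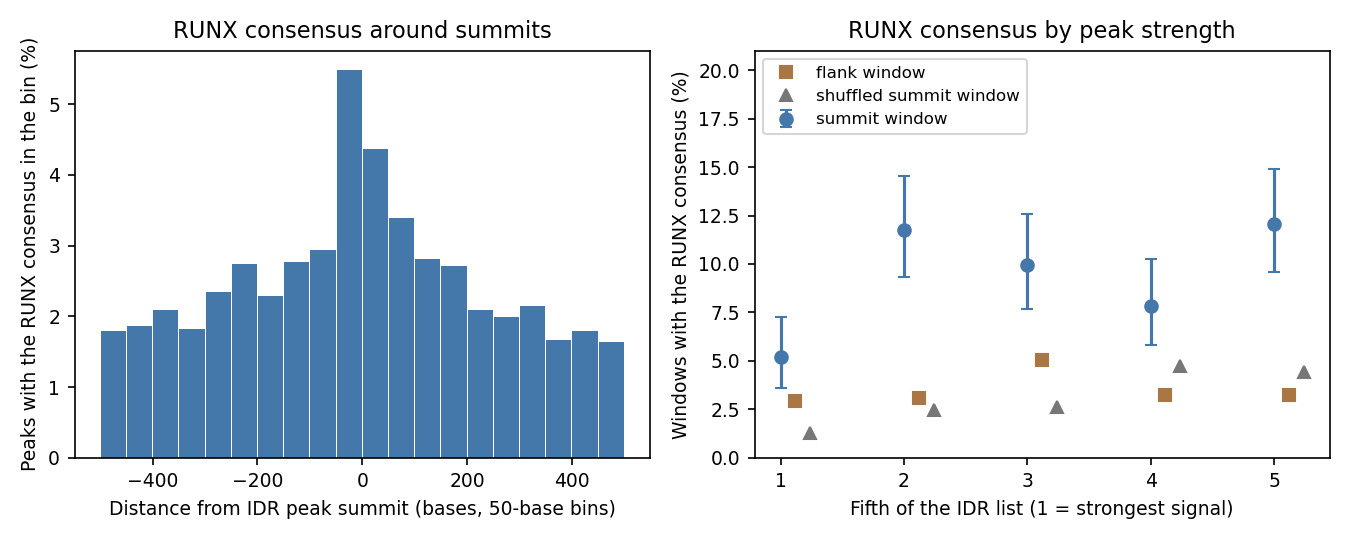
Left, the percentage of the 3065 IDR peaks with the RUNX consensus TGYGGTY in each bin of 50 bases around the summit; the highest bins, 5.48% and 4.37%, adjoin the summit. Right, the percentage of windows within 50 bases of the summit that held the consensus in 5 equal parts of the IDR list ranked by signal (613 peaks each, bars are 95% exact binomial intervals), with flank and shuffled windows as points; the strongest part had 5.22% and the weakest 12.1%.

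Within the IDR list, the consensus was less frequent in the 613 strongest peaks than in the 613 weakest. It occurred at 32 of the 613 strongest IDR summits (5.22%) and at 74 of the 613 weakest (12.1%), with p = 2.51e-05 in a two-sided Fisher's exact test. The intermediate parts of the ranking, at 11.7%, 9.95% and 7.83%, did not form a steady trend. The difference did not pass in the 2018 IDR peaks matched by strongest peaks of replicates 1 and 3, a shorter list that leaves replicate 2 out (-3.23 percentage points, exact p = 0.0760), or in the 6130 strongest pooled peaks (-1.63 points, p = 0.186). Over the whole pooled list the share ran the other way and was higher in stronger peaks. It was 9.4% at ranks 1 to 3000 and 9.87% at ranks 3001 to 6000. At ranks 24001 to 27000 and 27001 to 30000 it was 6.1% and 6.2%, and flanks held 3.37% to 4.6% throughout.

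Without a preset motif, the sequences most enriched at summits were made only of A and T. Of 2080 six-base sequences, with reverse complements merged, 304 were enriched at summits and 720 in flanks (exact McNemar tests, Benjamini-Hochberg adjusted p below 0.05). The 10 with the smallest p were AAATAT (34.1% of summit and 17.5% of flank windows), TTAAAA (30.9% and 15.4%), ATATTA, TAAATA, ATTTTA, ATTTAA, TATTAA, AAATAA, AATATT and AAAATA. Summit windows had a mean GC content of 34.4% ± 10.5 (SD over 3065 peaks) and flank windows 42.2% ± 10.3. Among sequences enriched at summits, the RUNX core TGCGGT ranked 61 (6.75% and 3.23%, exact adjusted p = 5.58e-09), TGTGGT 85, GTGGTT 90 and GCGGTT 207. The best-ranked RUNX core was GTGGTT at 106, 153 and 132 without replicate 1, 2 or 3, and TGCGGT at 13 in the 6130 strongest pooled peaks and at 25 with windows of 25 bases either side. Against summit windows shuffled with their dinucleotide counts kept, a background chosen after seeing the data, TGCGGT ranked 1 (6.75% and 1.99%, exact adjusted p = 9.46e-18).

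Among 13 consensus sequences fixed in advance, RUNX was the only one past the adjusted threshold against flanks in the IDR list. The GATA consensus was found at 10.1% of summits and 8.29% of flanks (exact adjusted p = 0.121) and the homeodomain consensus at 12.0% and 10.8% (exact adjusted p = 0.205). The site of DREF, a factor of housekeeping promoters, was at 0.718% and 0.359% (exact adjusted p = 0.149). Zelda (0.914% and 1.47%), GAGA factor (1.89% and 2.48%) and the E-box of Twist and Snail (7.05% and 8.29%) had values below those of flanks with exact adjusted p of 0.149, 0.205 and 0.149. The Bicoid, Tramtrack, Fushi tarazu factor 1, Odd-paired, Dichaete or SoxN, and Grainyhead sequences did not pass either, with adjusted p from 0.149 to 1. GATA passed in each replicate's own strongest peaks, at exact adjusted p of 0.000826, 0.00801 and 0.00246 for replicates 1, 2 and 3, with 10.3% ± 0.197 (SD, n = 3) of summits, and also with flanks at 1000 bases (0.00129), in the 6130 strongest pooled peaks (7.97e-05) and without replicate 3 (0.0473). The homeodomain consensus passed in replicates 1 and 3 alone (exact adjusted p = 0.0203 and 0.0230), without replicate 1 or 2 (0.0313 and 0.0212) and in the stronger part of the IDR list (0.00843), where GAGA factor passed as rarer than in flanks (0.00233). Against shuffled summit windows both turned: the difference was -3.00 percentage points for homeodomain (exact adjusted p = 0.00173) and 1.34 for GAGA factor (exact adjusted p = 2.90e-06). DREF passed in replicate 1 alone (exact adjusted p = 5.83e-05) and in the 6130 strongest pooled peaks (9.72e-05).

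The run gene itself carried 4 IDR summits within its span or 5 kb of it (chromosome X, 20690670 to 20697321, plus strand). The strongest ranked 174 in the list (summit at 20687396, signal 545) and lay in an exon of the long non-coding RNA CR43862, upstream of run. The next ranked 285 (20694213, signal 432) at an annotated start within run. The other two ranked 1371 (20689778, signal 202), between genes, and 2189 (20690693, signal 156), at the run start. These last 3 summits had the RUNX consensus within 50 bases, and the strongest did not. The tagged transgene encodes Runt, but whether it carries the DNA around run is not stated in the labels, and peak lists do not separate reads of 2 copies.

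**Figure D2:**
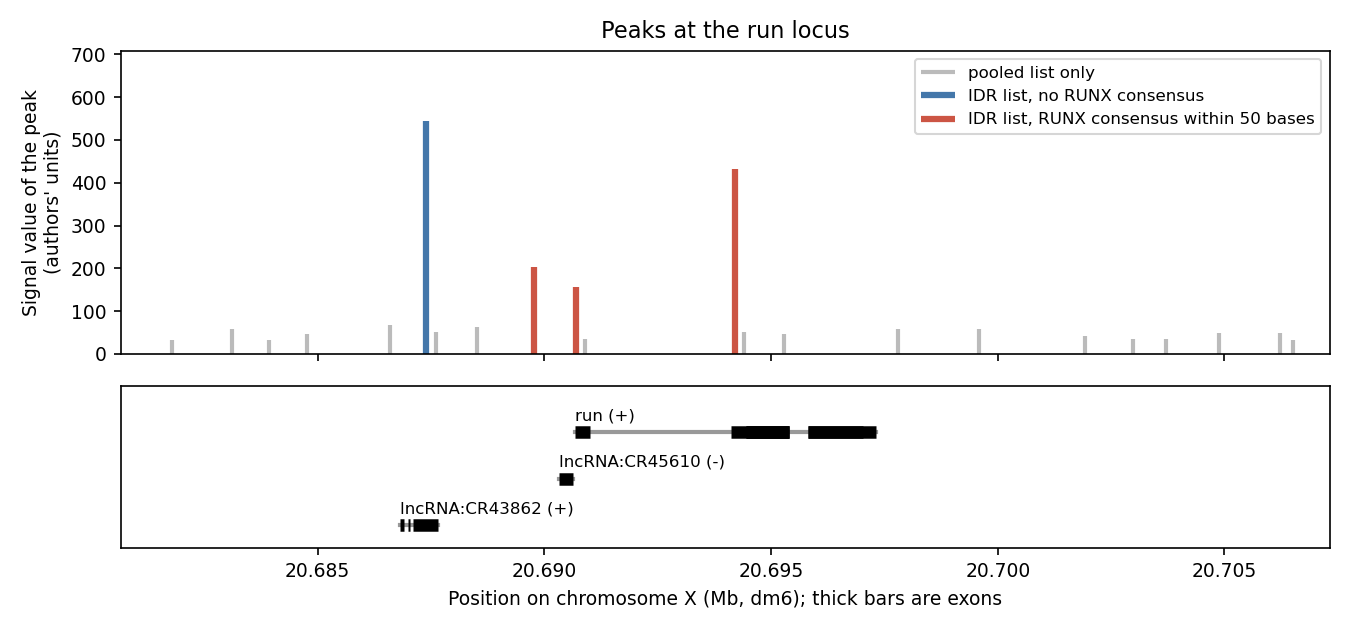
Signal values of peaks (in the authors' units) by position along chromosome X around run, with annotated genes and exons drawn below to scale. The 4 IDR summits near run, at ranks 174, 285, 1371 and 2189, stand above the peaks found only in the pooled list (grey).

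No excess of peaks was detected at segmentation genes over other genes of the same length. A protein-coding gene was counted as having a peak when an IDR summit lay in its span or within 5 kb. In all, 4714 of 13945 genes (33.8%) had one, and 1563 had several. A peak so counted can lie at a neighbouring gene and can count for more than 1 gene: of the 78 genes with a peak named from the lists here and below, 34 had their own start as the protein-coding start nearest to their strongest peak. Of the 9 pair-rule genes, only run and slp2 (strongest peak rank 232) did, against 3.25 expected from genes of the same span (exact adjusted p = 0.738), while eve, ftz, hry (hairy), odd, prd, slp1 and opa did not. Gap and head genes had 3 of 13, against 5.44 expected (cad, nub and ems; exact adjusted p = 0.655). Segment-polarity genes had 9 of 14, against 6.30 expected, led by ptc (rank 384), fz, nkd and dsh (exact adjusted p = 0.595). With each summit given to its nearest protein-coding start alone, segment-polarity genes had 7 against 3.73 expected (exact adjusted p = 0.154). Pair-rule genes then had 3 against 1.44 (0.324), and gap and head genes 2 against 2.99 (0.841). Lists this short can miss an excess: simulated lists of 15 genes with a true share of 60% were found in 43% of draws after adjustment. The embryos spanned 0 to 16 hours, so binding confined to part of this time could not be examined apart. Exact adjusted p-values here and below come from two-sided exact stratified permutation tests over gene span, Benjamini-Hochberg adjusted over 21 lists fixed in advance.

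Of the 12 sex-determination genes, run, the master switch Sxl (4 summits, strongest rank 543), gro, her and sisA had an IDR peak, against 4.32 expected (exact adjusted p = 0.800). The strongest summits for Sxl, her and sisA lay outside these genes, nearest to the starts of CG4615, CG31807 and Gapvd1. With the nearest start alone the list had 4 genes against 2.02 expected (exact adjusted p = 0.282). Summits were counted for neither sc, upd1, dpn, emc, da, tra nor msl-2. Among RUNX genes and their partners, run, gro and the CBF-beta homologs Bgb and Bro had a peak, against 3.09 of 7 expected (exact adjusted p = 0.800), and lz, RunxA and RunxB did not. Bgb and Bro are neighbours, and the peak at rank 290 was counted for both but lay nearest to the start of CG13919. The peak at rank 577, counted also for the neuronal gene nSyb, lay nearest to the Bgb start and carried the RUNX consensus.

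The cytoplasmic ribosomal protein genes stood out most. An IDR peak was counted for 63 of 92, against 25.8 expected (2.44 times, exact adjusted p = 9.01e-15), and for 62.7 ± 4.51 (SD, n = 3) in the replicates' own strongest peaks. The strongest peaks counted were those for RpL3 (rank 115), RpL27 (144), RpL34b (146) and RpS7 (186). The summit for RpL34b lay 152 bases upstream of its start but nearest to the start of CG8132. The other 3 lay beyond the 3′ ends of these genes, nearest to the starts of CG17726, Idh3g and CG9743. Mitochondrial ribosomal protein genes had 35 of 73, against 18.2 expected (1.93 times, exact adjusted p = 0.000103, replicates 35 ± 3). They were led by mRpS10 (rank 10), mRpL41 (11), mRpS23 (15) and mRpL19 (81). The summits for mRpS23 and mRpL19 lay nearest to the starts of CenG1A and CG8036. Proteasome genes, chosen by symbol, had 18 of 48, against 13.8 expected (exact adjusted p = 0.595). Their strongest peaks were counted for Rpt5, Rpn5, Prosbeta2R2 and Rpt6, each beyond the 3′ end of the gene. When each summit was given to its nearest protein-coding start alone, ribosomal protein genes had 53 against 7.99 expected (exact adjusted p = 5.04e-32) and mitochondrial ones 4 against 5.55 (exact adjusted p = 0.809).

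Genes of the Notch pathway and the Enhancer of split complex had a peak in 12 of 15 cases, against 5.10 expected (2.36 times, exact adjusted p = 0.000955; replicates 12 ± 1, SD, n = 3). The strongest were counted for E(spl)m3-HLH and E(spl)m4-BFM, which share the peak at rank 405, and for E(spl)m7-HLH and E(spl)m8-HLH, which share the peak at rank 511 with gro. Every listed gene of the Enhancer of split complex had a peak. Of the other members N, Ser and neur did as well, and Delta, Su(H) and H did not. The genes of the complex are neighbours on chromosome 3R, so their counts are not independent, and the list rests on 15 distinct summits. With the nearest start alone the list had 6 genes against 2.62 expected (exact adjusted p = 0.0849). Adult chemoreceptor genes, which encode odorant, gustatory and ionotropic receptors, had fewer peaks than matched genes, 26 of 179 against 56.2 expected (0.462 times, exact adjusted p = 1.87e-06; replicates 24 ± 3, SD, n = 3). Their strongest peaks were counted for Ir25a, Or85f, Gr5a and Ir68b. The peak of Or85f is the one counted for RpL34b, and that of Gr5a (rank 520) the one counted for RpL35.

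**Figure D3:**
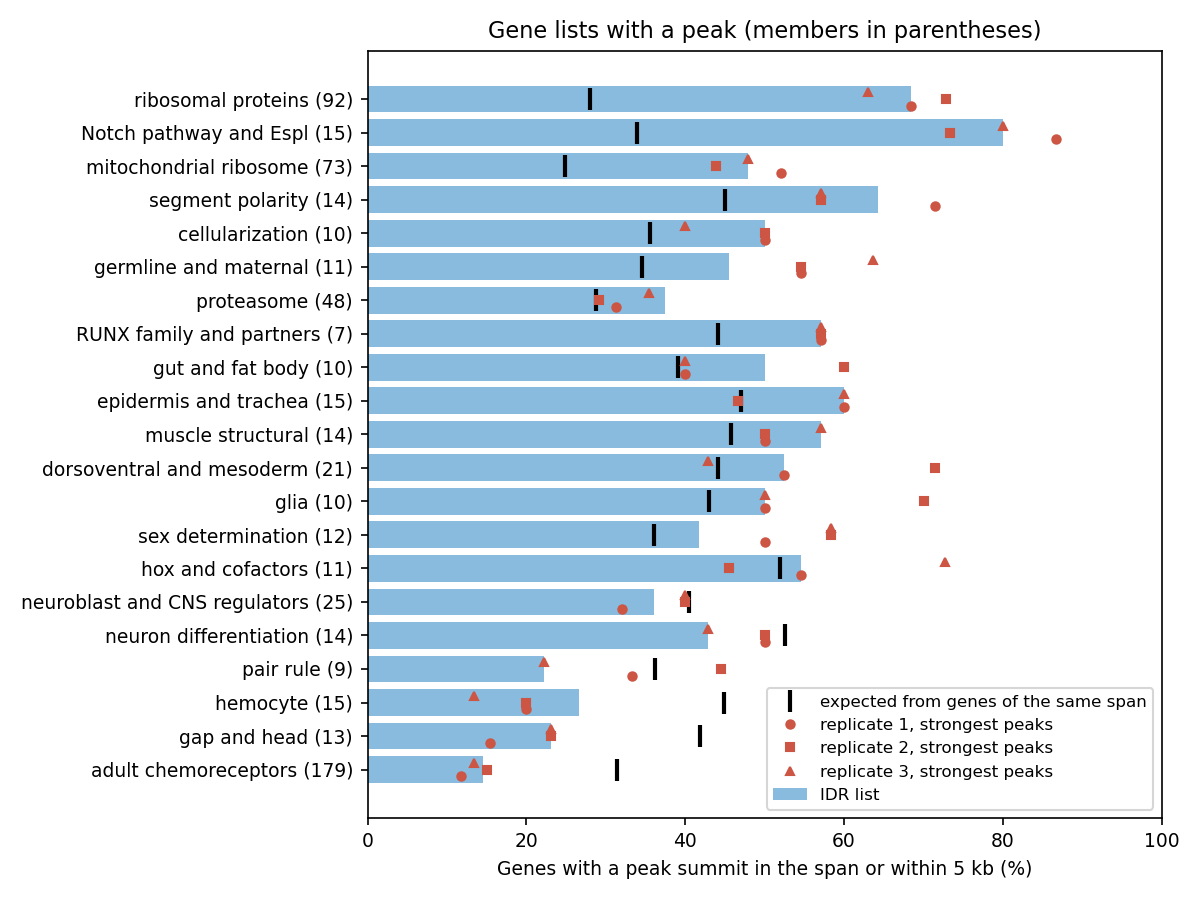
Percentage of genes in each of 21 lists with a peak summit in the gene span or within 5 kb, in the IDR list (bars) and in each replicate's own 3065 strongest peaks (red symbols); black ticks give the percentage expected from genes of the same span. Ribosomal protein genes had 68.5% against 28.0% expected and adult chemoreceptor genes 14.5% against 31.4%.

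The remaining developmental lists did not pass the test. Homeotic genes and cofactors had 6 of 11, against 5.72 expected (exact adjusted p = 1), and the peak at the promoter of the head homeotic gene Dfd, rank 43, carried the RUNX consensus. The other leading members were hth, Antp and Abd-B. Dorsoventral and mesoderm genes had 11 of 21, against 9.26 expected (exact adjusted p = 0.738), led by the muscle regulator Mef2 (rank 41), tin, tup and sim. The Mef2 summit lay 1075 bases upstream, nearest to the start of Pal1, and that of tup beyond its 3′ end, nearest to CG10602. With the nearest start alone the dorsoventral and mesoderm list had 11 genes against 5.47 expected (exact adjusted p = 0.0503). The other lists of this paragraph then ranged from 0 (germline and maternal) to 2.55 times expectation (gut and fat body), and none passed. Neuroblast regulators had 9 of 25 (exact adjusted p = 0.800), led by zfh2, pros, zfh1 and grh. Neuronal differentiation genes had 6 of 14 (exact adjusted p = 0.778), led by the pan-neuronal gene elav (rank 67), ChAT, nSyb and Gad1. The summits for ChAT, nSyb (rank 577) and Gad1 lay nearest to the starts of CG34283, Bgb and Faa. With the nearest start alone the neuronal list had 1 gene against 5.11 expected (exact adjusted p = 0.0849). Glial genes had 5 of 10 (exact adjusted p = 0.800), led by moody, Gs2, pnt and gcm2. Hemocyte genes had 4 of 15 (ush, Pxn, srp and Hml; exact adjusted p = 0.595) and gut and fat body genes 5 of 10 (fkh, bin, Adh and Fas3 led; exact adjusted p = 0.738). Muscle structural genes had 8 of 14, led by Tm1 (rank 117), Msp300, sls and Mhc, and epidermal and tracheal genes 9 of 15, led by the FGF gene bnl (rank 164), trh, sty and grh (both exact adjusted p = 0.738). Germline and maternal genes had 5 of 11, led by nanos, Yp3, bcd and vas, and cellularization genes 5 of 10, led by Trl (rank 13), Z600 (89), Sry-alpha and trbl (both exact adjusted p = 0.738). The peak of Sry-alpha, rank 394, lay beyond its 3′ end at the RpL32 promoter and is also counted there.

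Several genes had many summits in their span or within 5 kb, a count not adjusted for gene length. The most were at sbb, with 18 summits (chromosome 2R, 18278198 to 18357296), followed by CG1677 with 13, shn with 12 and ush with 11. CG14434, Rh5, Tlk and tara tied at 10. Rh5 spans 12008153 to 12009832 on chromosome 2L, and its strongest summit, rank 92, lay between genes and carried the RUNX consensus.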

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

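The report's results on sequence used the IDR list, the strongest peaks of each replicate and, as an alternative, the 6130 strongest pooled peaks. The weaker part of the pooled list, ranks 3066 to 30000, also held the RUNX consensus above its flanks. It occurred at 2012 of 26935 summits (7.47%) and in 1045 flank windows (3.88%), with p = 3.53e-73 in a two-sided exact McNemar test. This test was chosen after the data were seen. Single samples were not tested against the others, since a group of 3 is too small for that, and there was no second group.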

How the results depend on the processing

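Alternatives using the 6130 strongest pooled peaks, single replicates' own strongest peaks, shuffled windows for six-base sequences, and strata of span and neighbour distance were chosen after seeing the data. The promoter excess, the RUNX enrichment over flanks, and the results for ribosomal protein and chemoreceptor genes kept their direction and side of the threshold under every alternative run for them. Counting only peaks with the RUNX consensus, described further below, is not among these alternatives. Neither gene list passed there (both exact adjusted p = 0.658). The best-ranked RUNX six-base core kept its side of the threshold, with ranks from 1 (shuffled windows) to 153 (without replicate 2). Its direction could not change, since it was picked among sequences enriched at summits. Causes of the changes below were not tested. Depth is unknown, so its effect could not be examined.

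The share of IDR peaks found in all replicates was 78.9% with reciprocal 50% overlap, 88.2% with summits within 100 bases, 57.7% against each replicate's 3065 strongest peaks, and 99.3% to 99.5% without 1 replicate. Pairwise overlap of the strongest peaks was 60.8% and 62.2% under the same stricter rules, 74.2% with the 1532 strongest, 65.7% with 6130, and 67.7% to 71.9% without 1 replicate. Signal correlation was 0.753 by Pearson on log2 values, 0.700 in the stronger part of the IDR list, and 0.632 to 0.687 without 1 replicate. The X to autosome ratio was 0.850 with 6130 peaks, 0.884 in replicate 2 alone, and 1.06 per protein-coding gene. The strongest against weakest contrast for RUNX was -1.63 points with 6130 peaks and -5.36 to -3.23 without 1 replicate.

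Motifs enriched past the threshold numbered 1 with flanks at 500 bases, 2 in the stronger part of the list, 2 to 3 without 1 replicate (homeodomain, or Bicoid and GATA, besides RUNX), 3 with 6130 peaks, 4, 2 and 3 in replicates 1, 2 and 3 alone, 2 with flanks at 1000 bases and 3 with shuffled windows (RUNX, GAGA factor and DREF). Motifs rarer than the background past the threshold numbered 0 with flanks at 500 bases, 1 in the stronger part (GAGA factor), 0 to 1 without 1 replicate and 1 in replicate 3 alone (Fushi tarazu factor 1), and 3 with shuffled windows (Zelda, homeodomain and Tramtrack). Enriched gene lists numbered 1, not 3, within 1 kb of a start and 1 with the nearest start alone: the Notch list had 2.94 and 2.29 times expectation there (exact adjusted p = 0.0526 and 0.0849), and the mitochondrial ribosomal list 1.84 and 0.721 times (0.338 and 0.809), or 1.42 without strata (0.0673). Genes with a peak numbered 3006 in the stronger part of the list, 1905 within 1 kb of a start and 2072 with the nearest start alone.

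Motif differences (percentage points) that changed sign were, with shuffled windows, GAGA factor 1.34, E-box 1.34, homeodomain -3.00, Bicoid -0.392 and Tramtrack -0.848. Of these 5, GAGA factor, homeodomain and Tramtrack passed the threshold there. With flanks at 1000 bases they were E-box 0.359 and Tramtrack -0.685. With 6130 peaks they were Bicoid -0.0979 and Tramtrack -0.0653. In replicates alone, Tramtrack had -0.196 (1) and -0.228 (2). Grainyhead, whose difference was 0 and so had no sign to change, had 0.0653 with shuffled windows, -0.131 with flanks at 1000 bases, 0.0979 with 6130 peaks, -0.0326 in each replicate alone, -0.196 in the stronger part and -0.101 to 0 without 1 replicate, and passed in none of these.

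The mitochondrial ribosomal list thus reversed with the nearest start alone. Lists that passed under no setting also crossed expectation. With the nearest start alone these were pair-rule 2.08, neuroblast 1.29, germline 0 and proteasome 0.934. Within 1 kb of a start they were segment polarity 0.997, homeotic 0.357, germline 0 and proteasome 0.632. Within 2 kb of the span they were sex determination 0.989, muscle 0.965 and germline 0.397. Without strata, neuroblast had 1.06 and neuronal 1.27, with strata of span plus neighbour distance 1.01 and 1.20, and neuroblast had 1.20 with strata of both. With 6130 peaks they were pair-rule 1.26, neuronal 1.04, RUNX family 0.955 and cellularization 0.978, and in the stronger part neuronal 1.01 and gut 0.799. Replicate 1 alone gave gut 0.978, replicate 2 pair-rule 1.23, homeotic 0.869 and epidermal 0.985, and replicate 3 dorsoventral 0.970. Without 1 replicate the ranges were homeotic 0.859 to 1.11, glia 0.599 to 0.910, neuroblast 0.894 to 1.04, neuronal 0.835 to 1.04, gut 0.994 to 1.36, germline 0.713 to 1.04 and proteasome 0.978 to 1.24.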

Other observations

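Tests chosen only after the result was seen were those of gene crowding by strata of span and neighbour distance (the nearest start alone was planned), of RUNX sites at ribosomal protein genes, of single replicates, of GC content against rank, of summits below the IDR threshold and of the consensus at promoters, and those from the 20 repeated shuffles and the ratio to them. Peaks with the RUNX consensus differed in place from the rest. Of 287 such IDR peaks, 91 were at promoters, and the consensus was in 6.63% of promoter peaks and 11.6% of other peaks (two-sided Fisher's exact p = 2.63e-06). The strongest, named after their values were seen, were at the Dfd promoter (rank 43), on either side of Rh5 (ranks 92 and 103) and in introns of beat-VII (109), GlcAT-S (133), Btk (152) and bnl (164).

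No difference from other genes was detected in how many pair-rule genes had summits only below the IDR threshold. Of the 9 genes, 6 had such summits alone, against 4.27 expected from genes of the same span (exact stratified p = 0.322; 47.8% of all protein-coding genes): slp1 at pooled rank 3182, hry at 4314, ftz at 5173, eve at 5407, odd at 11677 and opa at 14319. For prd no peak was listed among the 30000. Of the gap and head genes, cad (680), nub (1843) and ems (2270) were in the IDR list, and the others had pdm2 at 4249, oc at 4439, knrl at 4450, btd at 4557, hkb at 10750, kni at 13642, tll at 19486, hb at 20702, Kr at 25742 and none for gt. That left 9 of 13 with summits only below the threshold, against 5.89 expected (exact stratified p = 0.0969). Of all protein-coding genes, 81.6% had some summit among the 30000.

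The hypothesis that peaks with the RUNX consensus mark developmental genes was tested on 7 developmental lists, counting those 287 peaks alone. None passed, the lowest adjusted p was 0.760 (exact stratified test), and 0 lists had an unadjusted p below 0.05. These counts are too few to decide: 0.355 to 1.46 genes were expected per list. Ratios as high as 2.82 (pair-rule, 1 gene) and 2.69 (Notch, 2 genes) did not pass. Dorsoventral and mesoderm genes, with 1.46 expected, and gap and head genes, with 0.767, had 0. The other lists had ratios from 1.11 to 1.89. The hypothesis stays open.

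The RUNX consensus was rarer in the strongest IDR peaks, at 5.22% against 12.1% of the weakest. A larger promoter share does not account for all of it: the difference held within promoter and other peaks taken apart (exact stratified p = 0.000551; 32 strong peaks with the consensus, 48.5 expected). Base composition that only adds to the share does not account for all of it: the excess over shuffled windows was -3.75 ± 1.82 (SE) percentage points, strongest minus weakest, with 1 shuffle and -4.99 ± 1.57 (SE) averaged over 20 further shuffles (-6.85 to -2.61 in single ones, with the 95% normal interval below 0 in 17). Composition acting in proportion cannot be told apart: the share over that of shuffled windows was 1.82 and 2.56 times, a ratio of 0.713 whose 95% bootstrap interval, 0.464 to 1.04, includes 1. Summit placement could also contribute and cannot be told apart: with 200 bases either side the shares were 20.7% and 25.1% (Fisher's exact p = 0.0772), which shows neither a difference nor equality; no biological explanation was tested.

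Ribosomal protein genes had more peaks than genes of the same span. Gene crowding does not account for it, since the list passed with the nearest start alone and with strata of span and neighbour distance, where the higher adjusted p was 1.5e-14. The excess was in every replicate (lowest ratio 2.18). With only peaks lacking the RUNX consensus counted it remained past the threshold (ratio 2.38, exact adjusted p = 2.41e-12). This setting leaves out only the 287 of 3065 IDR peaks that hold the consensus. Of promoter peaks at these genes, 3 of 56 (5.36%) had the consensus, against 6.69% of other promoter peaks. With consensus-bearing peaks alone the ratio was similar, at 2.29 (5 genes against 2.19 expected), but did not pass (exact adjusted p = 0.658). The excess was thus not shown to be particular to peaks without the consensus. For mitochondrial ribosomal protein genes crowding cannot be told apart: the excess was absent with the nearest start alone (exact adjusted p = 0.809) and present with those strata (1.54 times, exact adjusted p = 0.0138). Signal common to active promoters in any immunoprecipitation was not tested, as the control was not analysed here.

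Summits were richer in A and T than flanks. Promoter and exon composition does not account for all of it: for 1401 peaks with summit and flank both outside promoters and exons, GC was still lower at the summit, by -5.49 ± 0.386 (SE) percentage points. A preference of peak calling or enrichment for A- and T-rich sequence may contribute, since GC in the 6000 strongest of the pooled peaks lay -6.18 ± 0.184 (SE) points from that in the 6000 weakest. The direction required of this last test was first set down the wrong way round and was corrected after the value was seen, so it carries little weight. No biological explanation was tested.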
